A study of Mus musculus with 12 samples.

How the data were processed

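RNA of 12 male mice was measured with barcoded, gene-specific NanoString probes, per the labels' protocols. Mice began the diets at 12 to 18 weeks of age and stayed on them for 16 weeks, per the labels' protocols. A separate label gives diet durations that run from 16 to 27 weeks, 1 week more per mouse in deposited order, and it was not used. Labelled ages were 250 to 259 days in the knockout control mice and 252 in knockout Western-diet replicate 3. If these are ages at the end of the diet, they exceed what the protocol times allow. The start age or the time on the diet is then uncertain for these mice, all of them knockouts. The labels call the panel metabolic, but the 547 genes measured are mostly of the immune system. Groups were taken from the sample titles, which name genotype and diet, with 3 animals in each of 4 groups. Replicate numbers only name the libraries.

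The deposited workbook holds normalized counts on a log2 scale, per the file headers and the values. Within a library 2 to the power of the value was a whole multiple of 1 factor for 100% of values (tolerance 0.001), so the deposited log2 values are whole counts times a sample factor. How the authors set these factors, and with which reference genes or software, is not given in the sources used here. Whole counts recovered this way summed to 440842 to 643638 per library, and these totals limit the precision of low genes. The authors' deposited table also holds p-values and adjusted p-values for 1 comparison; the test behind them is not given in the sources used here. It states a log2 fold change threshold of 0.585, and 79 genes in the authors' deposited table pass both thresholds.

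The values were deposited as a workbook and as a series-wide value table, and these do not match. The columns of the value table hold the workbook's values shifted by 1 animal in deposited order. The workbook was used, because its header lines give animal number, diet and genotype as the sample titles do. Fold changes in the authors' deposited table followed the workbook's knockout minus wild-type difference on the Western diet with r = 0.985 across genes, against 0.462 for the value table. That table of fold changes is part of the same workbook. The comparison shows that the workbook follows its own labels, and is not separate support for them. Every group difference reported here rests on the choice of the workbook.

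The planned test took the deposited values to be linear. Since they were log2 values, they were returned to the linear scale, a pseudocount of 1 was added and log2 was taken again. Fold changes are on that scale, which understates the change of low genes. Genes with a mean of at least 20 normalized counts over the 12 libraries were tested, 453 of 547, and 94 were not. limma (version 3.58.1 in R 4.3.3) was fitted to all 12 libraries with a mean per group, a variance trend and moderated variances. Contrasts gave the genotype difference on each diet, the diet difference in each genotype and their interaction. P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison at a threshold of 0.05. With 3 mice against 3 an exact permutation test cannot give a p under 0.1, so none was used for single genes. Levels are means ± SD of normalized counts.

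Of 32 gene lists, 13 had no gene on the panel and 8 had panel genes but fewer than 5 tested, leaving 11. Among the lists without a tested result were hepatocyte markers, stellate cell and matrix genes, and sphingolipid metabolism. Each list was tested with limma's fry for movement in 1 direction, adjusted over the lists of a comparison. Fry does not compare a list with other genes. Camera, which does, was run with a preset correlation of 0.01 and with an estimated one. Some genes belong to more than 1 list.

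The groups, comparisons, tests, gene lists, the rule for named genes and most alternatives were set before the data were examined. The rule took in each comparison the 12 genes with the largest rise and the 12 with the largest fall among those that passed, or all if fewer. Where fewer than 10 passed it added the 5 higher and 5 lower genes with the smallest p-values, and from each list described up to 4 members with the smallest p-values. It also named Sphk2, Sphk1, Tnf, Il1b, Ccl2, Ccl5, Cxcl9, Cxcl10, Cd68, Cd3e, Cd8a and Col1a1 throughout, of which Sphk2, Sphk1, Cd68 and Col1a1 were not on the panel. Results of 1 gene that the rule selects are not reported here. Alternatives changed the pseudocount, filter, scaling, variance model, test, covariates, source of values and libraries. A planned count-model test was not run, because the deposited values are not counts, and rescaling on a list of reference genes was not run, because 1 gene of the list was on the panel. Alternatives without a pseudocount, recentred on the median ratio, with voom on recovered counts, and without both libraries that stood apart, and the overlap of calls with a fit per comparison, were added after seeing the data.

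The fit was tested on simulated data of 453 genes, with 200 changed between knockout and wild type on the Western diet. Over 20 simulations it recovered 55.2% of genes changed by 0.5 on the log2 scale, 88.5% of those changed by 1 and 100% of those changed by 2, with 2.85% false among the calls. A list moved by 0.5 was called in 20 of 20 simulations, and 6 of 220 tests of unmoved lists were called. The simulated genes varied independently, with 1 spread per gene in all 4 groups. Measured genes of a list were correlated, by up to 0.54 in the macrophage list, so these rates need not hold for the measured data. Of the panel genes, 545 matched a current symbol by Entrez identifier in a gene table of assembly GRCm38.p6, and 14 symbols differed; the files' symbols were kept. That table was used only for names and for gene order, and no coordinates are given. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.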

Results

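The expression of 547 mouse genes was measured with barcoded NanoString probes in 12 male mice on a C57BL6-NJ background. Sphingosine kinase 2 (SphK2), which makes the lipid signal sphingosine 1-phosphate, was intact in the wild type and knocked out in the other mice. Each genotype received either a control diet with normal water or a Western diet with sugar water, a feeding model of early metabolic dysfunction-associated steatohepatitis (MASH), an inflamed form of fatty liver. The 4 groups held 3 mice each. The liver is named by the title of the series and not by the sample labels. Whole counts recovered from the deposited values summed to between 440842 and 643638 per library, and the 10 most abundant genes took 46.9% to 58.4% of them. The probes did not include Sphk2 or Sphk1, so the knockout could not be checked in the RNA. Cd68 and Col1a1 were also not measured.

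The libraries separated mainly along a first principal component that held 58.9% of the variance of 453 tested genes. The 3 knockout libraries on the Western diet lay at 10.3, 11.6 and 10.4 on it, and the 6 control-diet libraries between -6.65 and -3.76. The wild-type Western-diet libraries lay at 5.29, -5.59 and 1.13, so replicate 2 of this group fell among the control-diet libraries. Knockout control-diet replicate 2 stood apart on the second component, at -9.00.

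On the Western diet, 19 of 21 macrophage and monocyte markers and 10 of 15 antigen presentation genes were higher in knockout than in wild-type mice. Neither list was called with an estimated correlation (adjusted p = 0.73 with an estimated correlation for each). Trem2, a receptor of lipid-handling macrophages, stood at 186 ± 23.1 normalized counts in the knockout and 58.3 ± 25.9 in the wild type (mean ± SD, n = 3), a log2 difference of 1.75 (SE 0.33). The alarmin genes S100a8 and S100a9, abundant in neutrophils and monocytes, were higher by 1.78 and 1.87, and Ccl2, which draws monocytes, by 1.71 (687 ± 117 against 241 ± 148). The protease gene Ctsc, which activates granule proteases of immune cells, was lower: 230 ± 26.9 against 915 ± 129, a log2 difference of -1.99 (SE 0.16). The metallopeptidase gene Mme differed by -1.40 and the NADPH oxidase gene Nox4 by -0.51. This comparison asked whether loss of SphK2 changes inflammatory gene expression once the Western diet is given.

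Of the 453 tested genes, 161 passed (limma with Benjamini-Hochberg adjustment, threshold 0.05), 146 of them higher and 15 lower in the knockout. The adjusted p was 1.91e-05 for Ctsc, 0.0044 for Trem2, 0.00583 for S100a8 and 0.0166 for Ccl2. In an equal-variance test per gene, which shares no spread between genes, 37 genes passed: Ctsc, Mme, Nox4 and Cdkn1a were among them, but Trem2, S100a8, S100a9, Ccl2, Defb1, Itgax, H2-Eb1, H2-Aa and H2-Ab1 were not (adjusted p = 0.0787 for Trem2, 0.0552 for S100a8 and 0.135 for Ccl2). The 3 knockout and 3 wild-type libraries did not overlap for 226 genes, 49.9% of those tested, where chance gives 10% on average. Here and in the other comparisons this share was counted under the authors' scaling only. Genes that move together enter it as a block, so its distance from 10% does not measure significance. The median gene differed by 0.26, and the split of calls depended on the scaling. With each library recentred on its median ratio, 69 genes were higher and 43 lower; after quantile normalization 42 were higher and 54 lower; and recentred on the sample median, which moved the median gene to -0.30, 26 were higher and 130 lower. Without wild-type Western-diet replicate 2, the library that lay among the control-diet libraries, 94 genes passed, and without knockout Western-diet replicate 2, 84 passed.

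Among the largest increases were also Defb1, an epithelial defensin gene (1.60), the integrin gene Itgax of dendritic cells and macrophages (1.35), the cell cycle inhibitor gene Cdkn1a (1.33), the chemokine gene Ccl6 (1.31) and Tlr2, a receptor for bacterial lipoproteins (1.26). The class II genes H2-Eb1, H2-Aa and H2-Ab1 rose by 1.42, 1.36 and 1.33; without knockout Western-diet replicate 2, H2-Aa and H2-Ab1 did not pass (adjusted p = 0.0542 and 0.0580 by limma). Those lower in the knockout included Cd1d1, which presents lipids to natural killer T cells (-0.65), the scavenger receptor gene Cd163 (-0.64), the interleukin 1 co-receptor gene Il1rap (-0.49), and the complement genes Masp2 (-0.42) and C8g (-0.35).

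Of 21 tested macrophage and monocyte markers, 19 rose and Cd163 fell (20 rose and 1 fell adjusted over the list alone). Csf1r, the receptor for the macrophage growth factor, rose by 0.84, the scavenger receptor gene Msr1 by 0.92, the tetraspanin gene Cd9 by 1.06 and the Fc receptor chain gene Fcer1g by 0.98. The list moved upward by fry (adjusted p = 0.00299). It was called by camera with a preset correlation (adjusted p = 0.000213) and not with an estimated one (adjusted p = 0.73 with an estimated correlation). The median marker differed by 0.91, by 0.66 after recentring on the median ratio, by 0.58 after quantile normalization and by 0.35 after recentring on the sample median. Without wild-type Western-diet replicate 2 the list's median was 0.66, with 12 markers rising and 0 falling.

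Of 15 antigen presentation genes, 10 rose (10 adjusted over the list alone; fry adjusted p = 0.00256, adjusted p = 0.73 with an estimated correlation). They included the protease gene Ctss (1.15) and Tapbp, which loads peptide on class I molecules (0.37, turning to -0.19 after recentring on the sample median). The list was not called after that recentring, at a median of 0.09. Of 6 endothelial markers 4 rose (6 adjusted over the list alone; fry adjusted p = 0.00191, adjusted p = 0.73 with an estimated correlation). The adhesion genes Vcam1, Icam1 and Sele, which bind leukocytes to the vessel wall, rose by 0.92, 0.98 and 0.76, and the junction gene Cdh5 by 0.50. Recentred on the sample median, Cdh5 stood at -0.07 and the endothelial list was not called (median 0.07).

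Among 54 cytokines, chemokines and their receptors, 21 rose and 1 fell (22 rose and 1 fell adjusted over the list alone; fry adjusted p = 0.00299, adjusted p = 0.83 with an estimated correlation). Examples were Il1a (0.81), the interferon gamma receptor gene Ifngr1 (0.67), Tgfb1 (0.93) and Csf1 (0.66). Of the inflammation genes fixed beforehand, Il1b (0.79), Ccl5 (1.02), Cxcl9 (1.22) and Cxcl10 (0.87) passed, with adjusted p-values of 0.0158, 0.0297, 0.0235 and 0.0286 by limma. Tnf (0.64), Cd3e (0.50) and Cd8a (-0.01) did not pass, at adjusted p-values of 0.152, 0.234 and 0.981. Of 35 genes of TLR, NOD and NF-kB signalling, 12 rose and 1 fell (12 rose and 1 fell adjusted over the list alone; fry adjusted p = 0.00256, adjusted p = 0.83 with an estimated correlation), among them Nfkb2 (0.88), Tlr4 (0.68) and Rela (0.36). Of 23 interferon response genes, 10 rose (13 adjusted over the list alone; fry adjusted p = 0.00603, adjusted p = 0.83 with an estimated correlation), including Irf8 (0.90), Stat2 (0.55) and Ifih1 (0.31). Recentring on the sample median moves the change of every gene by the same amount, and it took the medians of these 3 lists to -0.13, -0.26 and -0.26, each called downward. The cytokine median stayed above 0 in the other scalings, at 0.18 by the median ratio and 0.08 after quantile normalization, the latter without a call (fry adjusted p = 0.0502), and the TLR list was called downward at -0.15 after quantile normalization. Recentred on the median ratio, the interferon list was not called (median 0.05, fry adjusted p = 0.174).

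Of 24 T cell and NK cell markers Klrd1 (1.16), Cd7 (0.83) and Cd5 (0.57) rose (3 adjusted over the list alone; fry adjusted p = 0.0329, adjusted p = 0.83 with an estimated correlation), and the list's median was 0.18, with -0.07 after recentring on the median ratio and a downward call at -0.38 after recentring on the sample median. Of 7 B cell markers Blnk (0.93), Cd22 (0.71) and Btk (0.71) rose (4 adjusted over the list alone). The B cell list moved upward by fry (adjusted p = 0.00437) and was not called by camera with an estimated correlation (adjusted p = 0.83). Its median of 0.58 lay 0.32 above the median of all tested genes. Recentring on the sample median took the latter to -0.30, which left little of the list's rise. Of 5 dendritic cell markers Irf8 and Batf3 (0.61) rose (2 adjusted over the list alone; fry adjusted p = 0.00256, adjusted p = 0.83 with an estimated correlation). Cd7, Cd5 and Batf3 were low genes, at 22.1, 24.5 and 23.0 normalized counts in the wild type and 39.5, 36.9 and 35.9 in the knockout. Of 5 neutrophil markers S100a8 and S100a9 rose (3 adjusted over the list alone), but that list did not pass (fry adjusted p = 0.0813; 0.0274 without knockout control replicate 2). Of 9 genes of the p53 pathway and cell death, 3 rose, among them Cdkn1a and Trp53 (0.36) (3 adjusted over the list alone; fry adjusted p = 0.00299, adjusted p = 0.83 with an estimated correlation), with a downward call of the list at -0.24 after recentring on the sample median, where Trp53 stood at -0.20.

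Several of these calls did not pass when a single library was left out. This leaves 2 mice in a group, so a call near the threshold can be lost without that library being unusual. Without knockout Western-diet replicate 2, H2-Aa, H2-Ab1, Ccl6, Tlr4, Blnk, Ifih1, Cd22, Cd5, Cd7, Btk, Ccl5 and Cxcl9 were among those that did not pass, and without wild-type Western-diet replicate 2, Ccl2, Ccl6, Icam1, Sele, Cd22, Btk, Cd7, Il1b, Ccl5, Cxcl9 and Cxcl10. Without knockout Western-diet replicate 1, Ccl2, Icam1, Il1b, Cd5, Cd7, Ccl5, Cxcl9 and Cxcl10 did not pass. Cd163, C8g and Batf3 did not pass without replicate 2 or 3 of either Western-diet group, Cd163 also not without wild-type control replicate 3 or knockout control replicate 2 or 3, and Trp53 not without any 1 of 9 libraries. Sele and Ifih1 did not pass without wild-type Western-diet replicate 3 or knockout Western-diet replicate 2, Btk, Ccl5, Cxcl9 and Cxcl10 not without knockout Western-diet replicate 3, and Ccl5, Cxcl9 and Cxcl10 not without wild-type Western-diet replicate 3.

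**Figure D1:**
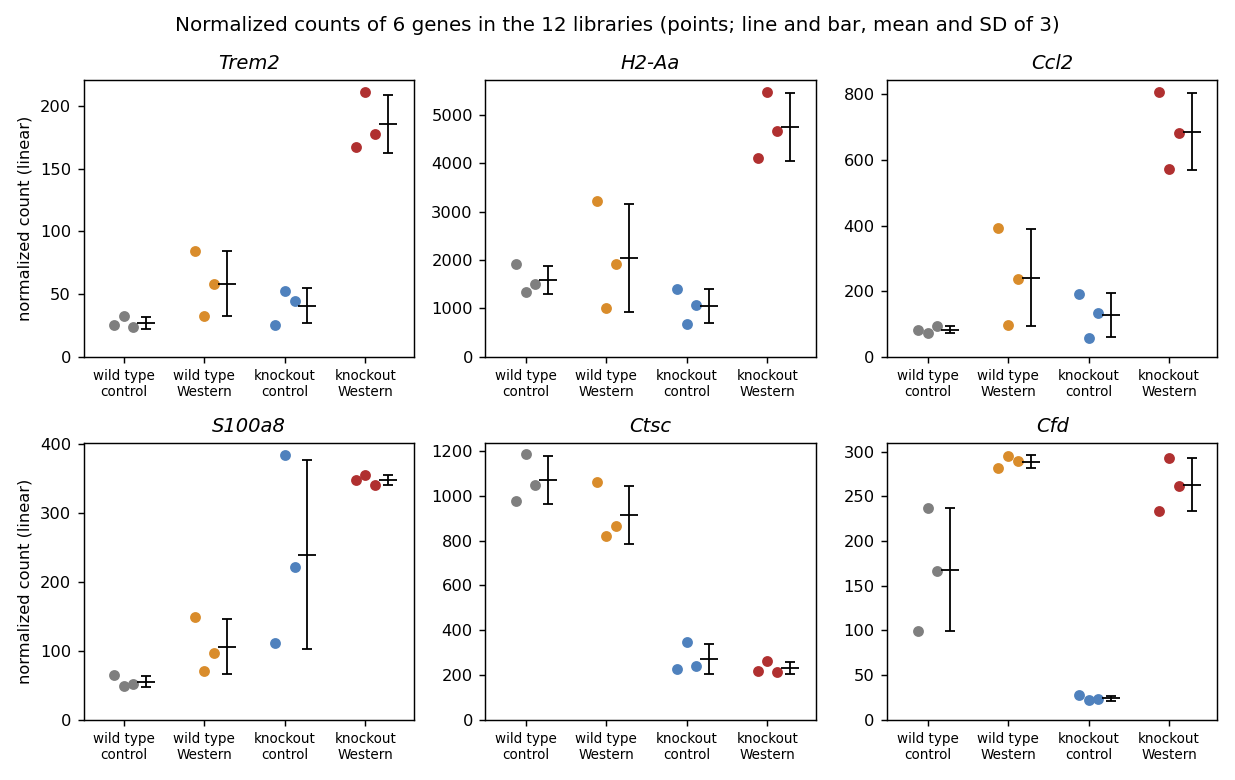
Normalized counts (vertical axes, linear, from 0) of 6 genes in the 12 libraries, as points in columns for the 4 groups, with a horizontal line and bar at each group's mean and SD (n = 3). Trem2, H2-Aa and Ccl2 were highest in the knockout on the Western diet, Ctsc was lower in both knockout groups, and Cfd stood at 23.9 in the knockout on the control diet against 168 in the wild type.

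The authors' deposited table, part of the workbook used here, holds fold changes and adjusted p-values for a comparison headed as SphK2 against wild type. In it 291 genes have a fold change other than 0. Fold changes in the authors' deposited table followed the Western-diet difference computed here across genes (Pearson r = 0.985, genes not being independent replicates). An adjusted p under 0.05 was given for 122 genes in the authors' deposited table, 106 of them higher and 16 lower. Of the 161 genes called here, 107 were also called in the authors' deposited table, all in the same direction, and 30 were listed there at a fold change of 0. A further 15 genes were called only in the authors' deposited table. Of the leading genes above, it called Ctsc, Defb1, Ccl6, H2-Eb1, H2-Aa and H2-Ab1, and listed Trem2, Itgax and Tlr2 at 0. It did not call Ccl2, S100a8, S100a9, Nox4, Mme or Cdkn1a. Their adjusted p-values there were 0.0511, 0.0731, 0.0731, 0.0862, 0.148 and 0.214, by a test that is not given. The genes it listed at 0 were low, with a median log2 level of 4.53.

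On the control diet, knockout mice differed from wild-type mice in a few genes. Cfd (complement factor D, adipsin), a protease of the alternative complement pathway that adipocytes secrete, stood at 23.9 ± 3.004 normalized counts in the knockout and 168 ± 69.0 in the wild type (n = 3), a log2 difference of -2.68 (SE 0.24). Mme differed by -2.49, Ctsc by -2.004 and Nox4 by -0.74. Cdkn1a was higher by 2.56 (SE 0.34; 474 ± 262 against 70.2 ± 5.15), and S100a9 and S100a8 were higher by 2.09 and 1.93. The circadian repressor gene Nfil3 rose by 0.74, the interleukin 6 signalling genes Stat3 and Il6st by 0.54 and 0.45, and Plaur, Cd5 and Litaf by 0.83, 0.66 and 0.48.

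These 13 genes, 9 higher and 4 lower, were all that passed (limma, Benjamini-Hochberg), at adjusted p-values of 3.28e-05 for Cfd, 1.75e-05 for Ctsc, 0.000711 for Cdkn1a and 0.0128 for S100a8; 77 genes had an unadjusted p under 0.05. Groups without overlap were seen for 108 genes (23.8%, where chance gives 10%). Recentred on the sample median, 5 genes were higher and 7 lower. The lists gave 0 calls by fry, where 1 had an unadjusted p under 0.05, and the smallest adjusted p was 0.305, for the neutrophil markers and the p53 list. By limma 2 of 5 neutrophil markers rose (2 adjusted over the list alone), as did 1 of 9 p53 genes (2 adjusted over the list alone), 1 of 54 cytokines and receptors (1 adjusted over the list alone) and 1 of 24 T and NK cell markers (1 adjusted over the list alone); of 23 interferon response genes 0 fell (1 adjusted over the list alone), and the other 6 lists held 0 calls either way. Camera with a preset correlation called antigen presentation downward (median -0.15, adjusted p = 0.00742), and with an estimated correlation called 0 lists (adjusted p = 0.614 for antigen presentation; 0 unadjusted). Of the fixed inflammation genes none passed by limma: Ccl2 was 0.47, Il1b 0.04, Ccl5 0.01, Tnf -0.36, Cxcl9 -0.87, Cxcl10 -0.29, Cd3e 0.18 and Cd8a 0.02.

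The 3 knockout control libraries spread widely for Cdkn1a (203 to 725) and S100a8 (111 to 384), and these mice were older, at 250 to 259 days against 231 to 232 in the wild type. With age in the model 5 genes passed, and S100a8, S100a9, Nfil3 and Stat3 were not among them. Within groups age varied mainly in the knockout on the Western diet, with an SD of 19.2 days against 0.58 to 4.58 in the other groups. The age term rests mainly on that group, so in no comparison can it well separate age from group. Without knockout control replicate 1, 43 genes passed; without wild-type control replicate 3 or knockout control replicate 3, 6 passed, and without wild-type control replicate 2, 8. S100a8, S100a9, Stat3 and Il6st did not pass without any 1 of these last 3 libraries, Il6st also not without wild-type control replicate 1 or knockout control replicate 2, and Plaur, Cd5 and Litaf not without most single libraries, those of the Western diet included. Cdkn1a, Nfil3, Cfd, Mme, Ctsc and Nox4 passed without each of the 12 libraries in turn, but not in the equal-variance test per gene, at adjusted p-values of 0.25, 0.107, 0.107, 0.24, 0.0762 and 0.0957. That test, run beside limma, called 0 genes in this comparison, with 60 at an unadjusted p under 0.05.

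Ctsc, Mme and Nox4 were lower in the knockout on both diets. The group means of the 2 diets share no library, but all 12 libraries set the spread, so the overlap of calls was also counted with each comparison fitted to its own 6 libraries, a check added after the result was seen. These 3 genes were shared either way, where independent lists would share 0.132 with all libraries in the fit and 0.159 in the separate fits (two-sided Fisher's exact test, p = 0.000116 and 0.000207, genes not being independent replicates). Cd5, Cdkn1a, Litaf, Plaur, S100a8 and S100a9 were called higher on both diets with all libraries in the fit, 6 genes against 2.9 (two-sided Fisher's exact test, p = 0.0346). The separate fits shared 2 genes, Cdkn1a and Cd9, against 0.788 (p = 0.17 by the same exact test), so an overlap beyond that of independent lists was not shown for the higher genes.

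In the wild type, the Western diet raised Cdkn1a from 70.2 ± 5.15 to 251 ± 35.9 normalized counts (n = 3), a log2 change of 1.82 (SE 0.34). Cish, an inhibitor of cytokine receptor signalling, rose by 1.66, the interleukin 1 receptor antagonist gene Il1rn by 1.48 and Ccr2, the receptor for Ccl2, by 1.44. The complement gene C8b fell by 1.38 and Nfil3 by 1.07. Other genes that fell were Ccl9 (-0.78), the interferon regulator gene Irf1 (-0.62), Abcb10 (-0.61), Il17rb (-0.58), Il18 (-0.58), Pigr (-0.53), Itga5 (-0.49), Irgm1 (-0.49) and Cxcl12 (-0.48). Plau, Plaur, Cd83, Tnfaip3, Cfd, Sele, Cybb and Vcam1 rose by 0.81 to 1.03.

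In all, 39 genes passed, 22 higher and 17 lower (limma, Benjamini-Hochberg), with adjusted p-values of 0.00108 for Nfil3, 0.0145 for Cdkn1a and 0.0243 for C8b. Groups did not overlap for 127 genes (28.04%, where chance gives 10%), and 114 had an unadjusted p under 0.05. Recentred on the median ratio, 17 were higher and 21 lower, and recentred on the sample median 11 were higher and 60 lower. The count turned on single libraries: without Western-diet replicate 2, 94 genes passed; without Western-diet replicate 3 or control replicate 3, 3 passed; without control replicate 1, 4; without Western-diet replicate 1, 12; and without control replicate 2, 23. It was 25 without knockout control replicate 3 and 22 without knockout Western-diet replicate 3, which enter only the estimate of the spread. Nfil3 and Cxcl12 alone of the genes named here passed without each of the 12 libraries in turn. In the equal-variance test per gene 2 genes passed, Cdkn1a among them, and Nfil3 and Cxcl12 did not (adjusted p = 0.0609 each).

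Of 6 endothelial markers Vcam1, Sele and Pecam1 (0.34) rose (3 adjusted over the list alone), and of 5 dendritic cell markers Bst2 (0.35), which is also an interferon-induced gene, rose (1 adjusted over the list alone). Both lists moved upward by fry (adjusted p = 0.0212 each), and neither with an estimated correlation (adjusted p = 0.719 with an estimated correlation). Both lost the call without any 1 of 5 libraries, wild-type control replicates 1, 2 and 3 and wild-type Western-diet replicates 1 and 3, where 0 lists passed fry. Of 21 macrophage and monocyte markers Ccr2 and Cybb rose (5 rose and 1 fell adjusted over the list alone), and the list did not pass (fry adjusted p = 0.294). Without Western-diet replicate 2, 14 of them rose and the list passed (fry adjusted p = 0.00564).

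The other 8 lists did not pass fry in the wild type, at adjusted p-values from 0.294 to 0.985, and for B cell markers (median -0.13), antigen presentation (0.04) and T and NK cell markers (0.05) the test pointed downward. Among 54 cytokines, chemokines and receptors 4 rose and 2 fell (4 rose and 2 fell adjusted over the list alone), and of the 9 p53 pathway and cell death genes Cdkn1a and Casp8 (0.26) rose and 1 gene fell (3 rose and 1 fell adjusted over the list alone). Casp8 stood at -0.02 after recentring on the sample median. Of 15 antigen presentation genes Tapbp fell (-0.30; 1 adjusted over the list alone), of 23 interferon response genes Bst2 rose and Irf1 fell (1 and 1 adjusted over the list alone), and of 35 TLR, NOD and NF-kB genes Casp8 and Tnfaip3 rose (0 adjusted over the list alone). The B cell, T and NK cell and neutrophil lists held 0 calls by limma. Of the fixed inflammation genes none passed: Ccl2 was 1.32 (adjusted p = 0.11), Cxcl10 0.57, Cd8a 0.20, Il1b -0.07, Ccl5 -0.09, Cd3e -0.27, Tnf -0.43 and Cxcl9 -0.81.

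In the knockout, the Western diet raised Cfd from 23.9 ± 3.004 to 263 ± 29.6 normalized counts (n = 3), a log2 change of 3.40 (SE 0.24). Ccl2 rose by 2.57 and its receptor Ccr2 by 2.31, and Trem2 by 2.22, from 40.7 ± 13.9 to 186 ± 23.1. The class II genes H2-Aa, H2-Eb1, H2-Ab1 and Cd74 rose by 2.23, 2.18, 2.15 and 1.91. The lymphocyte and macrophage receptor gene Slamf7 rose by 2.22, Itgax by 2.21, Il1rn by 2.08 and Defb1 by 2.01. Among the genes that fell were C8b (-1.99), the B cell chemokine gene Cxcl13 (-1.64), Nfil3 (-1.60), the iron hormone gene Hamp (-1.40), the scavenger receptor genes Cd163 (-1.15) and Marco (-0.93), Cd1d1 (-0.81) and Sigirr, a negative regulator of interleukin 1 receptors (-0.73).

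Complement genes made with C8b by hepatocytes were also among those that fell: Hc, which encodes C5 (-1.09), C8a (-1.05), C3 (-0.90) and the complement inhibitor gene Vtn (-0.86). Their control-diet levels spread widely, C3 from 50960 in replicate 1 to 108467 in replicate 2, the library that stood apart on the second component.

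With limma and Benjamini-Hochberg adjustment 205 genes passed, 169 higher and 36 lower, with adjusted p-values of 4.65e-06 for Cfd, 0.000329 for Trem2 and 0.000366 for C8b. In the equal-variance test per gene 159 passed, and Hamp, Hc, C8a, Marco, C3, Vtn, Bax, Il1b, Ccl5 and Cxcl9 were not among them. Groups did not overlap for 261 genes (57.6%, where chance gives 10%). The median gene changed by 0.27, and recentred on the median ratio 108 were higher and 96 lower; after quantile normalization 82 were higher and 111 lower; and recentred on the sample median, which moved the median gene to -0.46, 55 were higher and 228 lower. With age in the model 92 genes passed and the interferon and p53 lists were not called (fry adjusted p = 0.0504 and 0.144), the knockout mice being 250 to 259 days old on the control diet and 217 to 252 on the Western diet. As on the control diet, this model cannot well separate age from group.

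Of 21 macrophage and monocyte markers 19 rose, and Cd163 and Marco fell (19 rose and 2 fell adjusted over the list alone; fry adjusted p = 0.00112, adjusted p = 0.712 with an estimated correlation). Cybb rose by 1.54, the signalling adaptor gene Tyrobp by 1.37 and Fcer1g by 1.20. The list's median was 1.11, and 0.39 after recentring on the sample median. All 5 dendritic cell and all 6 endothelial markers rose (5 and 6 adjusted over the list alone; fry adjusted p = 6.85e-05 each, adjusted p = 0.554 with an estimated correlation), among them Irf8 (1.37) and Bst2 (0.61), and Vcam1 (1.44), Sele (1.17) and Pecam1 (0.66). Recentred on the sample median, Bst2 stood at -0.12 and Pecam1 at -0.07, and neither list was called (medians 0.06 and 0.05). Of 15 antigen presentation genes 10 rose (11 adjusted over the list alone; fry adjusted p = 0.00112, adjusted p = 0.712 with an estimated correlation), and after recentring on the sample median 7 rose and 5 fell, with a median of -0.21 and no call.

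Of 54 cytokines, chemokines and receptors 27 rose and 4 fell (29 rose and 4 fell adjusted over the list alone; fry adjusted p = 0.00112, adjusted p = 0.712 with an estimated correlation), with Il1a at 1.23 and Cxcl12 at -0.52. Of 35 TLR, NOD and NF-kB genes 17 rose (18 adjusted over the list alone; fry adjusted p = 0.00112, adjusted p = 0.712 with an estimated correlation), such as Tlr4 (1.29), Relb (1.28), Nfkb2 (1.04) and the inflammasome protease gene Casp1 (0.94). Of 23 interferon response genes 11 rose and 1 fell (11 rose and 1 fell adjusted over the list alone; fry adjusted p = 0.00316, adjusted p = 0.712 with an estimated correlation), with Irf7 at 1.18 and Ifngr1 at 0.74. Recentred on the sample median, all 3 lists were called downward, at medians of -0.29, -0.40 and -0.46. After quantile normalization the TLR list was called downward too, at -0.08.

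Of 9 p53 pathway and cell death genes 4 rose (4 adjusted over the list alone; fry adjusted p = 0.00515, adjusted p = 0.907 with an estimated correlation), including Trp53 (0.53) and Bax (0.37), which turned to -0.20 and -0.36 after recentring on the sample median, where the list was called downward (-0.39). Of 7 B cell markers the signalling genes Blnk (1.62) and Btk (1.28), which myeloid cells also express, rose (2 adjusted over the list alone). The B cell list moved upward by fry (adjusted p = 0.00112) and was not called by camera with an estimated correlation (adjusted p = 0.712). Its median of 0.38 lay 0.11 above the median of all tested genes. Recentring on the sample median took the latter to -0.46, which turned the list's median downward. Of 24 T cell and NK cell markers the NK receptor genes Klrd1 (1.25) and Klrk1 (0.75) rose (2 adjusted over the list alone), and neither this list (fry adjusted p = 0.195) nor the 5 neutrophil markers, with 0 rising by limma (0 adjusted over the list alone; fry adjusted p = 0.355), passed. Of the fixed inflammation genes Cxcl10 (1.72), Cxcl9 (1.29), Ccl5 (0.92) and Il1b (0.67) passed by limma, and Tnf (0.57), Cd8a (0.17) and Cd3e (0.05) did not. Il1b did not pass without knockout control replicate 1 or knockout Western-diet replicate 1 or 3, and Ccl5 not without any 1 of 6 libraries. Il1b stood at -0.06 after recentring on the sample median or quantile normalization, and Cd3e was called lower (-0.68) after the former.

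Of the genes that fell with the diet, 9 were called in both genotypes where independent lists would share 1.35 (two-sided Fisher's exact test, p = 7.12e-07, genes not being independent replicates), including C8b, Nfil3, Abcb10, Il18, Pigr, Itga5 and Cxcl12. With each genotype fitted to its own 6 libraries, so that no library entered both, 7 were shared against 0.596 (p = 1.27e-07 by the same exact test). They were C3, C8b, Cd1d1, Cxcl12, Nfil3, Pigr and Vtn. Of the genes that rose, 19 were called in both with all libraries setting the spread, against 8.21 (two-sided Fisher's exact test, p = 1.75e-06), among them Il1rn, Ccr2, Plau, Plaur, Cd83, Tnfaip3, Cfd, Sele, Cybb and Vcam1. The separate fits called 9 higher genes in the wild type and shared 3 of them, Bst2, Cd36 and Cd83, against 3.28 (p = 1 by the same exact test), so an overlap beyond that of independent lists was not shown for the genes that rose.

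**Figure D2:**
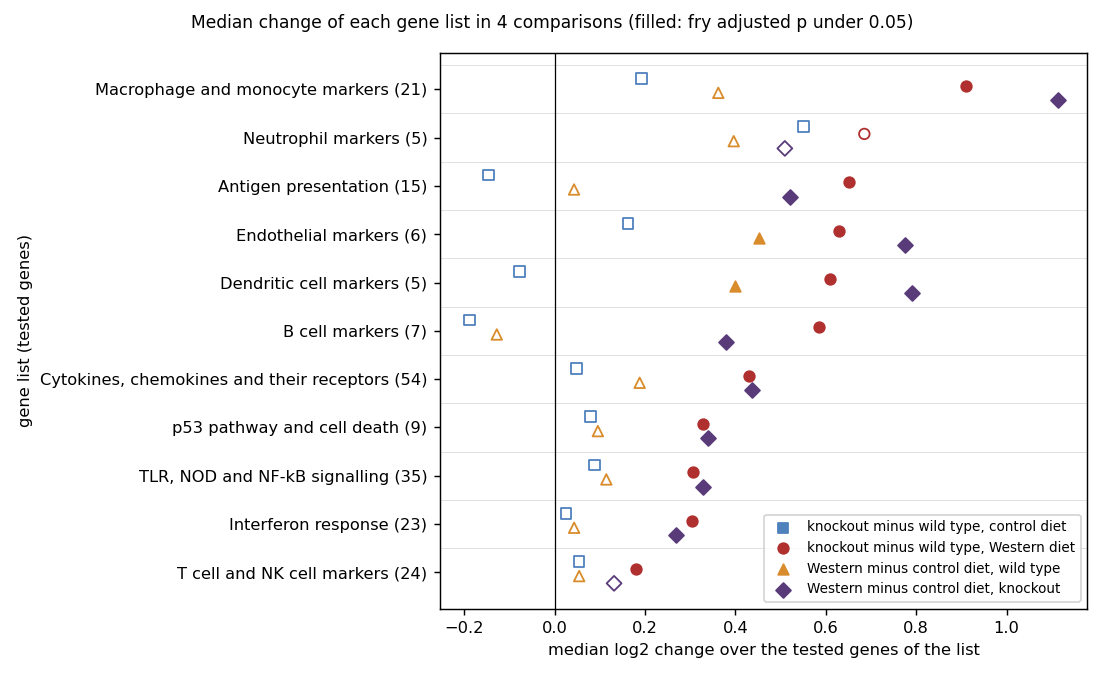
Median log2 change (horizontal axis) over the tested genes of 11 gene lists (vertical axis, number of tested genes in brackets) in 4 comparisons, with filled symbols where the list passed fry at an adjusted p under 0.05 and open symbols where it did not. Macrophage and monocyte markers lay at 0.91 for knockout against wild type on the Western diet and at 1.11 for the diet in the knockout; recentring on the sample median brought these to 0.35 and 0.39 and turned the cytokine, TLR, interferon, T cell and p53 lists downward in both.

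The interaction asked whether the diet changed a gene by a different amount in the knockout than in the wild type. Cfd rose more in the knockout, by a further 2.54 (SE 0.34): from 23.9 to 263 normalized counts, against 168 to 289 in the wild type. The class II gene H2-Eb1 went from 214 to 947 in the knockout and from 345 to 386 in the wild type, a difference of 2.14 (SE 0.46), and Il1a from 84.5 to 199 and from 83.8 to 113, a difference of 0.80 (SE 0.15). The interferon regulator gene Irf1 (0.78) and Tapbp (0.50) stood lower on the Western diet in the wild type (555 against 855, and 622 against 764) and not in the knockout (684 against 617, and 804 against 699). Ltbr, a receptor for lymphotoxin, went from 1196 to 1503 in the wild type and from 1411 to 1241 in the knockout, a difference of -0.51 (SE 0.11).

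These 6 genes, 5 higher and 1 lower, passed (limma, Benjamini-Hochberg), Cfd at an adjusted p of 0.00427 and the other 5 at 0.0414, while 142 genes had an unadjusted p under 0.05. Cd1d1 (-0.47), Masp2 (-0.44), the death receptor gene Fas (-0.55) and the proteasome gene Psmc2 (-0.31) did not pass, at adjusted p-values from 0.0535 to 0.0603. Of the fixed inflammation genes none passed: Cxcl9 was 2.09 (adjusted p = 0.0535), Cxcl10 1.15 (0.0818), Il1b 0.74, Ccl5 1.01, Tnf 1.0, Ccl2 1.24, Cd3e 0.31 and Cd8a -0.03. Cfd passed without each of the 12 libraries in turn and with age in the model. It was the 1 gene that passed with age, and likewise without any 1 of wild-type control replicates 1 and 3, wild-type Western-diet replicate 3, knockout control replicates 2 and 3, and all 3 knockout Western-diet libraries. The count was 100 without wild-type Western-diet replicate 1, 58 without knockout control replicate 1 and 11 without wild-type control replicate 2.

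By fry 7 lists moved upward in the interaction. They were antigen presentation (median 0.86, adjusted p = 0.0117), B cell markers (0.72, 0.0176), dendritic cell markers (0.38, 0.0184), endothelial markers (0.37, 0.0219), cytokines and their receptors (0.40, 0.0473), interferon response (0.31, 0.0473) and TLR, NOD and NF-kB signalling (0.23, 0.0491). The adjusted p with an estimated correlation was 0.643 for antigen presentation, 0.737 for TLR, NOD and NF-kB signalling and 0.662 for the other 5. Antigen presentation held H2-Eb1 and Tapbp (12 genes adjusted over the list alone), the cytokines Il1a (3 adjusted over the list alone) and the interferon list Irf1 (7 adjusted over the list alone). The B cell, dendritic cell, endothelial and TLR lists held 0 single-gene calls by limma, with 2, 1, 1 and 0 adjusted over the list alone. Macrophage and monocyte markers missed the threshold (median 0.73, fry adjusted p = 0.0583), as did the T and NK cell (0.328), p53 (0.251) and neutrophil (0.715) lists. With age in the model or recentred on the sample median, fry called 0 lists, with 4 and 3 at an unadjusted p under 0.05, and the median turned to -0.05 for cytokines, -0.14 for interferon response, -0.22 for TLR, -0.08 for endothelial and -0.07 for dendritic cell markers in the latter. Without single libraries the number of lists lay between 3 and 8, the lowest without knockout control replicate 1 or 3, knockout Western-diet replicate 1 or 2, or wild-type control replicate 3.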

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

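The regroupings of samples were planned, and the tests of a wrong diet label, library depth, sample factors, cell shares and linked DNA were chosen only after the result was seen. The diet response differed between the genotypes, by the interaction in limma, for Cfd (2.54), H2-Eb1 (2.14), Il1a (0.80), Irf1 (0.78), Tapbp (0.50) and Ltbr (-0.51). By fry it differed for antigen presentation (median 0.86), B cell markers (0.72), cytokines and their receptors (0.40), dendritic cell markers (0.38), endothelial markers (0.37), interferon response (0.31) and TLR, NOD and NF-kB signalling (0.23). No list was called with an estimated correlation (adjusted p = 0.643 to 0.737 with an estimated correlation), and fry called 0 lists with age in the model (4 unadjusted) or after recentring on the sample median (3 unadjusted). When genotype was reassigned within each diet, 4 of 100 regroupings drawn at random from 200, the real one included, gave at least 6 genes. The highest other gave 11, and the share lay under 0.05 by 1 regrouping, for this draw. Reassigning genotype also breaks up the genotype difference on each diet, which then enters the spread. The regroupings therefore test for no genotype effect at all, and cannot decide whether chance gave the interaction calls. The other 4 comparisons each have 10 splits of 6 libraries, too few for a share under 0.05: 1 of 10, the real one, gave as many genes (161, 13, 39 and 205), and the highest other split gave 0.

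Wild-type Western-diet replicate 2 lay with the control-diet libraries on the first component. A control diet fed under a wrong label was argued against: of 36 genes that fell with the diet in the knockout, 66.7% lay below all 3 wild-type controls in this library, where chance gives 25% and the other 2 libraries of its group gave 75.0% and 69.4%. Their median deviation was -0.21, against -0.02 to 0.07 for single wild-type controls, where a control diet would leave them at the controls' level. The 169 genes that rose with the diet in the knockout went with a wrong label: 30.2% lay above all 3 controls, against 84.6% and 72.8% in the other 2 libraries, and their median deviation was -0.020, near the -0.016 to 0.0010 of single controls and away from 0.61 and 0.35 in the other 2. Lower depth was argued against too, since its total of 464820 lay between 440842 and 476529; a weaker inflammatory response of this mouse may remain, and was not tested.

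Most genes that passed between the genotypes on the Western diet were higher in the knockout. The authors' sample factors alone would shift genes of every abundance alike, but the 67 genes with a mean of at least 1000 had a median of -0.017, outside the 0.16 to 0.40 that held 95% of random gene sets; which genes mark no change, and the split of higher and lower calls, stay open. A lower share of hepatocyte RNA, which would raise all other cell types alike, cannot be told apart from a macrophage response: 19 macrophage markers rose by 0.32 (SE 0.15) more than 5 endothelial markers, but the libraries overlapped (0.67 to 0.79 in the knockout, 0.17 to 0.68 in the wild type). These endothelial markers include the adhesion genes Vcam1 (0.92) and Icam1 (0.98), which may themselves respond to inflammation, so this comparison cannot separate the explanations. Of its other members, Cdh5 rose by 0.50, and Pecam1 stood at 459 normalized counts in the knockout against 393 in the wild type. T and NK cell markers were tried first, and macrophage markers rose by 0.44 (SE 0.19) more than these, without overlap (1.82 to 1.95 in the knockout, 1.23 to 1.81 in the wild type), which goes against a lower hepatocyte share. That test was set aside because it rested on 2 genes with a mean of at least 50, and the requirement of no overlap was added after that, so the explanation is left open on few markers.

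Ctsc and Nox4 were lower in the knockout on both diets, and lie on chromosome 7, as Sphk2 does. A candidate explanation is DNA carried along with the targeted gene. Among other tested genes of the chromosome 1 of 32 was called the same way on both diets, against 6 of 419 elsewhere (two-sided Fisher's exact test, p = 0.405), which decides nothing about a short stretch. Ctsc and Nox4 have 2 protein-coding genes between them, and Nox4 and Sphk2 have 252. Neither passed in the interaction (0.02 and 0.23), so linked DNA and loss of SphK2 cannot be told apart for these genes.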

How the results depend on the processing

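The tests without a pseudocount, recentred on the median ratio, by voom, and without both libraries that stood apart were chosen only after the result was seen; the others were planned. No paired analysis was possible because the labels give no shared replicate numbers. The count test and the rescaling on reference genes were not run. Counts are given for genotype on the Western diet, genotype on the control diet, diet in the wild type, diet in the knockout and interaction (161, 13, 39, 205 and 6 genes; 10, 0, 2, 9 and 7 lists). Low genes were limited by depth: between 75 and 132 genes lay below 20 normalized counts per library. Unless a setting's construction shows it, the cause was not tested.

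Pseudocount 10 gave 23 interaction genes. Without the filter the interaction gave 2 genes and 4 lists. With a mean of at least 50 it gave 39 genes and 4 lists, and diet in the wild type 0 lists by fry (2 unadjusted). Recentred on the sample median, the 5 comparisons gave 156, 12, 71, 283 and 66 genes and 6, 1, 7, 6 and 0 lists (3 unadjusted in the last, by fry). After quantile normalization they gave 96, 23, 42, 193 and 27 genes and 5, 1, 2, 9 and 3 lists, and recentred on the median ratio 112, 21, 38, 204 and 37 genes. Higher against lower in the interaction were 7 and 59, 13 and 14, and 16 and 21 under these 3 scalings. With age, which the model cannot well separate from group, 5, 18, 92 and 1 genes passed after the first comparison, and 0 interaction lists by fry (4 unadjusted). With only the 2 groups compared, genotype on the control diet gave 7 genes and 1 list, and diet in the wild type 19 genes and 0 lists by fry (3 unadjusted), fewer samples setting the spread. The equal-variance test per gene gave 37, 0 (60 unadjusted), 2 and 159 genes. Without a variance trend, diet in the wild type gave 21 genes and the interaction 2. Array weights, whose estimation did not converge, gave 259, 119, 184, 293 and 193 genes and 10, 2, 6, 9 and 8 lists. Without both libraries that stood apart, diet in the wild type gave 114 genes and 5 lists. Camera with a preset correlation gave 2, 1, 0 (3 unadjusted), 3 and 2 lists, and with an estimated one 0 in each (0 unadjusted). Fry for change in either direction gave 1 list for genotype on the control diet and 5 for diet in the wild type. Leaving out single libraries gave 84 to 177, 6 to 43, 3 to 94, 165 to 212 and 1 to 100 genes, and 9 to 11, 0 to 2, 0 to 5, 9 and 3 to 8 lists. Pseudocount 0.5, no pseudocount, the robust variance prior and voom kept every count within 1.5 times.

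With the columns of the value table, which hold another animal's values, limma called 0 genes in each comparison (45, 45, 22, 49 and 71 unadjusted) and fry 0 lists (0, 3, 0, 1 and 2 unadjusted). Named genes turned direction there. For genotype on the Western diet these were H2-Eb1 -0.40, H2-Aa -0.37, H2-Ab1 -0.37, Cd163 0.36, Tlr4 -0.033 and Cxcl9 -0.25. For genotype on the control diet they were Cdkn1a -0.42, S100a9 -1.15, S100a8 -1.11, Plaur -0.57, Cd5 -0.18, Stat3 -0.062, Litaf -0.15, Il6st -0.054, Mme 0.33, Ctsc 0.52 and Nox4 0.070. For diet in the wild type they were Cdkn1a -1.45, Il1rn -0.98, Ccr2 -0.87, Plau -0.82, Plaur -0.89, Cd83 -0.62, Tnfaip3 -0.43, Sele -0.61, Cybb -0.73, Vcam1 -0.85, C8b 0.33, Nfil3 0.16, Abcb10 0.23, Il18 0.17, Cxcl12 0.32, Pecam1 -0.21, Bst2 -0.17 and Casp8 -0.14. For diet in the knockout they were Cfd -1.42, C8b 0.95, Cxcl13 0.42, Nfil3 0.68, Hamp 0.53, Cd163 0.015, Hc 0.70, C8a 0.83, Marco 1.04, C3 0.74, Vtn 0.57, Sigirr 0.090, Cxcl12 0.049, Bst2 -0.066 and Cxcl10 -0.089, and for the interaction Cfd -1.61.

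Recentred on the sample median, which lowers all genes of a library alike, genotype on the Western diet turned for Tapbp -0.19, Rela -0.20, Cdh5 -0.067, Stat2 -0.0097, Ifih1 -0.25 and Trp53 -0.20, diet in the wild type for Casp8 -0.019, and diet in the knockout for Pecam1 -0.071, Bst2 -0.12, Il1b -0.058, Cd3e -0.68, Trp53 -0.20 and Bax -0.36. After quantile normalization Rela -0.00844 and Trp53 -0.15 turned for genotype on the Western diet, and Il1b -0.063, Trp53 -0.15 and Bax -0.066 for diet in the knockout. Recentred on the median ratio 0 named genes turned.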

Other observations

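The complement list was chosen only after its values were seen, and so were its tests under other scalings. Of 25 complement genes, 12 fell and 4 rose with the Western diet in the knockout by limma, at a median of -0.43, and in the wild type 1 fell and 1 rose, at -0.05; the difference between these responses passed for 1 gene, Cfd, which was higher, at a median of -0.33. That difference depended on the scaling: 1 gene was higher and 5 lower after recentring on the median ratio (median -0.53), 1 higher and 10 lower after recentring on the sample median (-0.78), and 2 higher and 1 lower after quantile normalization (-0.027). The fall was seen at -0.70 after recentring on the median ratio, -1.16 after recentring on the sample median and -0.11 after quantile normalization. Knockout control replicate 2 held the most complement RNA, its median gene lying 0.70 above the mean of the 12 libraries, against 0.21 and -0.09 in the other 2 libraries of its group and -0.14 to -0.13 in the knockout on the Western diet. Without it 9 fell and 4 rose, at a median of -0.26, with age in the model 6 fell and 4 rose, and after quantile normalization 8 fell and 5 rose. In the wild type C3 went from 48516.5 to 37960.4 normalized counts with the Western diet, and Vtn from 10614.7 to 8586.32. With each genotype fitted to its own 6 libraries, C8b, C3 and Vtn were called lower with the diet in both genotypes. For these genes the fall was not limited to the knockout. The complement list was not tested as a set.

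The macrophage receptors did not all move together. In the knockout the Western diet lowered Marco, from 229 to 125 normalized counts, and Cd163, from 112 to 50.01, both abundant in resident macrophages of the liver (Marco without a call in the equal-variance test per gene, adjusted p = 0.102), while Trem2 went from 40.7 to 186 and Itgax from 31.4 to 146. In the wild type Marco went from 130 to 74.2, Cd163 from 93.6 to 79.5, Trem2 from 27.1 to 58.3 and Itgax from 27.2 to 62.4. The interaction did not pass by limma for these 4 genes, at adjusted p-values of 0.807, 0.0873, 0.109 and 0.119. With 3 mice per group this does not show that the genotypes responded alike.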
